A study of Mus musculus with 4 samples.

How the data were processed

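Gene expression was measured by RNA sequencing in tooth germs dissected from mouse embryos of day 14.5. Per the labels' protocols, total RNA was purified with Trizol and a Qiagen column kit, libraries were built with the PrepX SPIA kit on an Apollo 324 instrument, and sequencing was done on an Illumina HiSeq. There were 4 libraries, 1 in each of 4 groups: a Yap conditional knockout (CKO), its litter control, a YAP transgenic (Tg) and its control. The labels put the first pair on a C57BL/6 background and the second pair on an FVB background. All libraries were used and none was merged with another. The number of embryos behind each library is not known here.

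Each library had 1 table of 20207 genes, whose coordinates are on build mm9 per the submitters' processing notes. The aligner, the counting program, the annotation and any strand setting are not given in the sources used here. The estimated counts were deposited by the authors as read counts per gene with 4 significant digits. Of the nonzero counts below 1000, 77.7% to 79.2% were whole to within 1e-06. The RPKM values were deposited by the authors beside the counts, per the file headers, and express reads scaled by gene model length and by library depth. The score column, deposited by the authors as a Z-score, agreed to within 0.0101 with RPKM minus its mean over genes, divided by its standard deviation within the library. The signal column, deposited by the authors as RMS-normalized RPKM, matched RPKM divided by its root mean square over genes: the median ratio of the 2 columns in the CKO litter control was 81.3, as was that root mean square. The last 2 columns are rescalings within a library and were used only to check what the files hold. No symbol was repeated for the CKO litter control, and no counts were summed.

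For 274 genes the coordinates differed between the 4 files. A gene's model was called different within a pair when its coordinates differed, or when the model length implied by count over RPKM differed by more than 5% with at least 10 reads in both libraries. This held for 127 of 14018 genes tested in the CKO pair and 113 of 13936 in the Tg pair. Counts of such genes cover different stretches of the genome in the 2 libraries, so their ratios are marked where named. Of 379 genes of the fixed gene lists with a measurement, this concerned 3 in the CKO pair and 2 in the Tg pair (Etv1, Sox5 and Ifi27l1 in all).

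The estimated counts were rounded to whole numbers and converted to counts-per-million values (CPM) on library sizes scaled with the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. TMM factors were 1.01, 1.00, 0.999 and 0.989 for the CKO litter control, Yap CKO, Tg control and YAP Tg libraries. Differences are log2 ratios of CPM plus a pseudocount of 1, which understates the difference of low genes. Genes entered a comparison with at least 1 CPM in either library of the pair. Folds given without a pseudocount carry a 95% interval, the exact Clopper-Pearson interval of the split of a gene's reads between 2 libraries. These intervals cover counting error only, since amplified reads are not independent molecules. Among genes of 1 to 20 reads, 52.2% to 54.4% of the rounded counts were even. Rounding may give this, since it takes a count midway between 2 whole numbers to the even one. Both mates of some pairs may instead each have been counted, and the intervals are then too narrow. Intervals of the genes fixed by name were therefore also computed on halved counts, a choice made after seeing the data. A count of 0 was bounded with 3 counts in that library.

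With 1 library per group no spread between animals can be estimated, so no p-value, standard deviation or test between conditions is given. The 2 controls were compared with each other as a yardstick, although they differ in strain and litter. Each control also enters the ratio of its own pair, so the yardstick is not independent of the pairs. The counts of genes shared by the 2 genotype comparisons, which share no library, were set beside the number expected for independent lists. The median log2 ratio of each gene list was placed among 10000 random lists of the same size matched on mean expression in 50 bins, as a description of these libraries. There were 26 lists of 405 symbols, fixed before the data were examined together with the rule for named genes, of which 4 symbols had no match. List members were measured with at least 1 CPM in any library. A further 3 lists were chosen after seeing the data and appear only in the closing observations.

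The named genes were, per comparison, the 10 with the highest and the 10 with the lowest log2 ratio among genes with at least 5 CPM in either library. Small RNA genes, gene models named Gm, Rik or LOC, mitochondrial genes and sex-linked genes were left out of this ranking. Yap1, Hoxa1, Hoxc13, Ctgf and Cyr61 were named in both comparisons. Up to 4 members per list and comparison with the largest absolute ratio were added, or the most abundant members for lists of other cell types, and up to 15 genes at least 1.5-fold different in opposite directions.

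Counts were simulated for 13932 genes in the CKO pair and 13942 in the Tg pair, with changes made only in genes averaging at least 5 CPM. Of those made 3-fold or 6-fold different, 100% were called at least 2-fold different in the right direction, and 0 unchanged genes were. Changes in lower genes were not tried, and there the pseudocount can hide them. Hoxc13, with a fold of 0.347 in the CKO pair, had a log2 ratio of -0.64. The simulation holds counting noise only. The alternatives tried were library totals, DESeq2 1.42.0 size factors and upper-quartile scaling in place of TMM, pseudocounts of 0.1 and 5, a minimum of 5 CPM or none, and leaving out small RNA and hemoglobin genes. Added after seeing the data were the deposited RPKM in place of CPM, leaving out X and Y genes, and leaving out genes of differing models. Figures were drawn with matplotlib 3.10.9.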

Results

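Tooth germs of mouse embryos of day 14.5, when the molar is at the cap stage and the enamel knot signals to the folding epithelium, were profiled in 4 libraries. A Yap conditional knockout was set against its litter control on C57BL/6, and a YAP transgenic against its control on FVB. Yap is the transcriptional co-activator restrained by the Hippo kinase pathway, and the series title names Hoxa1 and Hoxc13 as its downstream targets. The libraries held 62012308 counts in the CKO litter control, 63193582 in the Yap CKO, 66580618 in the Tg control and 56920928 in the YAP Tg, and between 13723 and 13881 genes reached 1 CPM (counts-per-million value). Each group had 1 library, so no difference below has a replicate check, and every value describes these libraries. Intervals are 95% exact Clopper-Pearson intervals for counting error only.

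Yap1 itself was lower in the knockout and higher in the transgenic, by modest amounts. It was counted at 288 CPM in the CKO litter control and 208 CPM in the Yap CKO, a fold of 0.720 (0.704 to 0.736). It was counted at 294 CPM in the Tg control and 373 CPM in the YAP Tg, a fold of 1.27 (1.24 to 1.29), while the 2 controls differed by a fold of 1.02. Of 1208 genes of like abundance, 7 had a log2 ratio as low as that of Yap1 in the CKO pair and 17 had one as high in the Tg pair. Yap1 lies on chromosome 9 from 7932001 to 8004588 (mm9). The labels do not say which exons were deleted, in which cells, or from which species the transgene came, so this checks the labels only in part.

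Hoxa1 and Hoxc13, both homeobox transcription factors, were low in all 4 libraries, at 0.180 to 3.91 CPM. Hoxa1 (chromosome 6, 52105366 to 52108316) had 38 reads in the CKO litter control and 15 in the Yap CKO, a fold of 0.390 (0.20 to 0.727). It had 12 reads in the Tg control and 145 in the YAP Tg, a fold of 14.3 (7.93 to 28.3), and none of 1457 genes of like abundance was as high. The 2 controls differed in Hoxa1 by a fold of 0.297 (0.141 to 0.581), further apart than the CKO pair. Hoxc13 (chromosome 15, 102751562 to 102759245) had 77 and 27 reads in the CKO pair, a fold of 0.347 (0.215 to 0.544). It had 134 and 220 reads in the Tg pair, a fold of 1.94 (1.56 to 2.42), against a fold of 1.64 between the controls. On halved counts the Hoxa1 interval widened to 0.158 to 0.996 in the CKO pair and 6.2 to 39.9 in the Tg pair, and the Hoxc13 interval to 0.182 to 0.688 and 1.42 to 2.67. The series title credits sequencing with finding both genes, so they may have been chosen on these libraries and are not counted as independent evidence of a direction. Of 39 Hox genes listed, 8 were measured, with a median log2 ratio of -0.31 in the CKO pair and 0.13 in the Tg pair. The Tg median was -0.05 with a minimum of 5 CPM and -0.07 by RPKM.

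**Figure D1:**
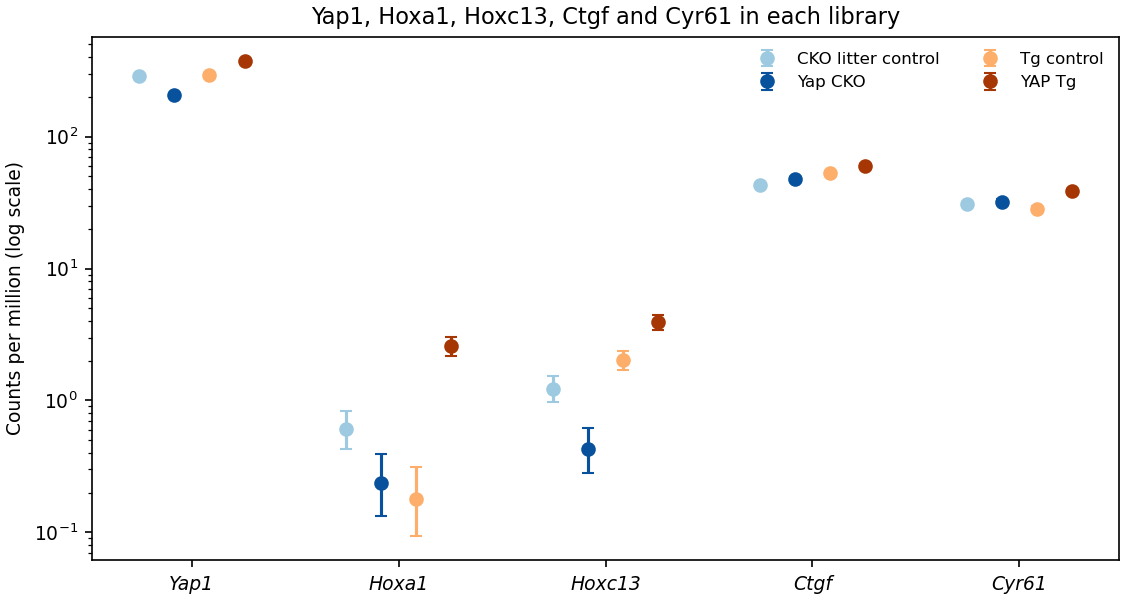
CPM (log scale) of Yap1, Hoxa1, Hoxc13, Ctgf and Cyr61 in each of the 4 libraries, 1 point per library, with exact 95% Poisson intervals for counting error only, which are smaller than the point for abundant genes. Yap1 sits at 208 CPM in the Yap CKO and 373 CPM in the YAP Tg, and Hoxa1 stands at 2.57 CPM in the YAP Tg against 0.180 CPM in its control.

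The Yap CKO library was compared with its litter control to ask which genes differ when Yap is removed. Of 23 dental epithelium genes 20 were lower in the Yap CKO, 6 of them by at least 1.5-fold. Keratinocyte differentiation genes were split, 14 of 24 lower and 10 higher, with 4 at least 1.5-fold higher, 2 at least 1.5-fold lower and a median log2 ratio of -0.16. Wnt3a, a secreted Wnt ligand, had 5.69 CPM (356 reads) in the control and 0.569 CPM (36 reads) in the Yap CKO, the lowest log2 ratio of the named genes in this pair at -2.09. Krt6b and Krt16, keratins of activated and oral epithelium, were 12.1-fold (10.1 to 14.5) and 12.5-fold (10.3 to 15.3) higher. Skeletal muscle and bone lists were higher too, with medians of 0.26 and 0.59. At the 2-fold mark, 32 of 14018 genes were higher and 38 lower, against 41 and 22 of 13996 between the 2 controls.

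Among the genes furthest below the litter control were 2 adhesion molecules. Itgb4, the integrin beta 4 of hemidesmosomes, stood at 0.397 of its control level (0.378 to 0.417), and Bcam, a laminin receptor, at 0.397 (0.384 to 0.409). The keratin Krt77 stood at 0.227 (0.212 to 0.244) and the annexin Anxa8 at 0.373 (0.347 to 0.401). Il17re, an interleukin 17 receptor chain, stood at 0.243, and Casp14, a caspase of cornifying cells, at 0.291. Ano9 and the epidermal transcription factor Pou2f3 stood at 0.358 and 0.389. Serpinb10 stood at 0.297 by counts, with a gene model that differed between the 2 files, and had 3.24 and 0.892 RPKM. Among the highest were Cdsn, the corneodesmosin of cornified cell junctions, at 13.0-fold (9.69 to 18.0), and Rptn, the envelope protein repetin, at 7.83-fold (6.68 to 9.22). Krt76, a palatal and gingival keratin, was 10.9-fold higher (7.85 to 15.6), and Spink5, an epidermal protease inhibitor, 3.34-fold (3.05 to 3.66). Sprr3, a small proline-rich envelope protein, was 3.13-fold higher, Arg1 3.72-fold and Idi2 2.87-fold. Dtna was 3.40-fold higher by counts but had 1.26 and 1.12 RPKM, its gene model being different in the 2 files. Krt6b, Krt16, Krt76 and Sprr3 belong to families of similar sequence, so reads may be split between relatives.

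The dental epithelium list was lower as a group. Its median log2 ratio was -0.43, below each of the 10000 random lists. The epithelial transcription factor Grhl2 had a log2 ratio of -0.79, the splicing regulators Esrp2 and Esrp1 -0.76 and -0.60, E-cadherin (Cdh1) -0.68 and Trp63, the p63 of basal cells, -0.65. The basal keratins Krt5 and Krt14 had -0.56 and -0.51, while Krt8 had 0.21 and Sox21 0.20. Pitx2, Sostdc1 and Foxi3 had -0.24, -0.30 and -0.18. The skeletal muscle list lay the other way in this pair, with 18 of 18 members higher, 0 by at least 1.5-fold, and a median of 0.26. So did bone, with 7 of 7 higher, 4 by at least 1.5-fold, and a median of 0.59. Cartilage had a median of 0.37, against 0.27 between the controls, and endothelium 0.23, against 0.08.

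The stratified keratinocyte differentiation list was split. Its median lay below each of the 10000 random lists, while its mean was 0.03. Between the 2 controls the list had a median of -0.17, also below each random list. The CKO litter control is the reference of both medians, so the CKO median cannot be told apart from a difference in that library. Krt6a had a log2 ratio of 1.42 (92 and 247 CPM), the envelope precursor Sprr1a 1.33, Krt13, a keratin of internal stratified epithelia, 1.24 (151 and 359 CPM) and Cnfn 0.92. Krtdap had -0.87 (62.8 and 34.0 CPM) and Krt10, a keratin of epidermal suprabasal cells, -0.86 (534 and 293 CPM).

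The enamel knot list and the targets of Wnt and Hedgehog signalling had medians below 0, and those of FGF and BMP signalling did not. Of 18 enamel knot genes 12 were lower, 3 by at least 1.5-fold, with a median of -0.30. Shh, the hedgehog ligand of the knot, had 22.6 and 11.3 CPM, a log2 ratio of -0.95, and Wnt6 and Wnt3 had -0.89 and -0.64. The ligands Fgf4, Fgf3, Fgf20 and Bmp2 were among the 6 higher members, Fgf4 with 0.56 at 1.74 and 3.03 CPM. Of 15 Wnt/beta-catenin targets 13 were lower with a median of -0.30, among them Notum at -0.39 and Axin2 at -0.37, and no member was 1.5-fold different. Of 8 Hedgehog targets 6 were lower with a median of -0.21, Ptch2 at -0.40 and Hhip, the hedgehog-interacting protein, at -0.36, and again no member was 1.5-fold different. Of 11 FGF/ERK targets 9 were higher with a median of 0.11, and of 12 BMP targets 8 were higher with a median of 0.03 that was -0.0017 by RPKM. The epithelium of the tooth germ makes Shh, Wnt6 and Wnt3, and the dental epithelium list had its median of -0.43 in the same pair.

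Of 22 cell cycle genes 21 were lower by a small and even amount, with a median of -0.19, for example Mki67 at -0.30 and Aurkb at -0.33. No member was 1.5-fold different. The YAP/TAZ target signature had a median of 0.04, at percentile 90.5 of random lists, and 0 of its 22 members were 1.5-fold different. Ctgf and Cyr61, matricellular proteins widely used as Yap readouts, had folds of 1.11 (1.05 to 1.17) and 1.04 (0.976 to 1.11). Between the controls their folds were 1.24 and 0.921. Among 22 Hippo pathway components the median was near 0, and Wwc1, the upstream regulator Kibra, was the only one at least 1.5-fold different, at -0.59.

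The number of 2-fold genes depends on the weight given to low counts. It was 151 with a pseudocount of 0.1, 18 with a pseudocount of 5, and by RPKM 19 higher and 13 lower. Erythroid genes were lower in the Yap CKO with a median of -0.47, smaller than the median of -0.72 between the controls. The CKO litter control is the reference of both medians, so high values in that library alone could give both. In the Tg pair the erythroid median was -0.01.

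The YAP Tg library was compared with its control to ask which genes differ when YAP is added. Of 24 keratinocyte differentiation genes 19 were lower in the YAP Tg, 13 of them by at least 1.5-fold, and of 23 dental epithelium genes 17 were higher, 2 by that much, and 6 lower. Krt7, a simple epithelial keratin, was 3.13-fold higher (2.94 to 3.33; 21.9 and 68.4 CPM), and Slc2a3, the glucose transporter GLUT3, 2.83-fold higher (2.71 to 2.95). Krt13 stood at 0.235 of its control level (0.222 to 0.249) and Krt6a at 0.262 (0.245 to 0.280). Rptn had 339 reads in the control and 0 in the YAP Tg, 95.6-fold lower if 3 counts stand in for the 0. Its interval is wider, reaching 0.0129 of the control level, and 0.0259 on halved counts. Skeletal muscle and bone lists were lower as well, with medians of -0.57 and -0.84. At the 2-fold mark, 29 of 13936 genes were higher and 47 lower.

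Among the highest genes, Bmp8b, a bone morphogenetic protein, was 4.24-fold higher (3.31 to 5.50; 81 and 291 reads) and Arhgap22 2.91-fold (2.59 to 3.28). Klrg2, Phyhip, Lipg, an endothelial lipase, and the rhomboid family member Rhbdl3 were 2.79-fold, 2.75-fold, 2.75-fold and 2.64-fold higher. Fgfbp1, a carrier protein that releases fibroblast growth factors, was 2.29-fold higher (2.13 to 2.46). Serpinb8 was 3.12-fold higher by counts and had 1.87 and 2.26 RPKM, its gene model being different in the 2 files. Among the lowest, the serpins Serpinb3a and Serpinb12 stood at 0.0711 (0.0537 to 0.0925) and 0.157 (0.123 to 0.197) of their control levels. Sprr3 stood at 0.0518, Dhrs2 at 0.0960 and Idi2 at 0.144. Cyp26c1, an enzyme that breaks down retinoic acid, stood at 0.139 (0.117 to 0.163), with 20.7 CPM in the Tg control against 10.6 CPM in the CKO litter control. The bone matrix genes Spp1 (osteopontin) and Dmp1 stood at 0.182 (0.163 to 0.202) and 0.174 (0.151 to 0.20). Serpinb3a and Sprr3 have close relatives in the genome, so reads may be split between them.

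The keratinocyte differentiation list had a median log2 ratio of -0.73, and 0 of its members were at least 1.5-fold higher. Beside Krt13 at -2.05 and Krt6a at -1.88, Cnfn had -1.64 and Calml3, a calmodulin-like protein of differentiating keratinocytes, -1.55. Krt10 had -0.86 (612 and 336 CPM), as low as in the Yap CKO. Between the 2 controls this list had a median of -0.17.

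The dental epithelium list had a median of 0.26, above each of the 10000 random lists. Cldn4, a tight junction protein, had 0.81, Krt14 0.67 (727 and 1159 CPM), Grhl2 0.58 and Krt5 0.57 (1753 and 2601 CPM), while Ovol1, a transcription factor of differentiating epithelium, had -0.31. Of the 23 members 17 were higher. Sostdc1 and Foxi3 were among the 6 lower ones, at -0.27 each, and Pitx2 had 0.12. In the same pair 18 of 18 skeletal muscle genes were lower, 9 by at least 1.5-fold, with a median of -0.57; Myh3, embryonic myosin, had 630 and 433 CPM. Of 7 bone genes 7 were lower with a median of -0.84, Ibsp (bone sialoprotein) having 516 and 225 CPM. Cartilage had a median of 0.20, against 0.27 between the controls. The sex-linked genes also differed: Xist, expressed from the inactive X, had 761 and 1513 CPM, and the Y gene Ddx3y 47.0 and 26.9 CPM. The labels give no sex. Both libraries held reads of both genes, so each may mix the sexes. A difference in sex mix is not separated from genotype in this pair.

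Of 18 enamel knot genes 12 were higher with a median of 0.19, close to the 0.18 between the 2 controls. Wnt6 had 54.1 and 113 CPM (1.05), Wnt3 0.74 and Wnt10b 0.71, whereas Shh had 31.6 and 20.2 CPM (-0.62). In the CKO litter control Shh had 22.6 CPM, a log2 ratio of 0.46 between the controls. Of 8 Hedgehog targets 6 were lower with a median of -0.25, Hhip at -0.76 and Ptch1, the hedgehog receptor, at -0.41. Of 15 Wnt/beta-catenin targets 11 were higher with a median of 0.21, Znrf3 at 0.50 and Notum at 0.48, while Dkk1 and Dkk4, secreted Wnt inhibitors, had -0.61 and -0.55. FGF/ERK targets had a median of 0.15 over 11 genes, 7 of them higher, and BMP targets 0.02 over 12, 6 of them higher. The 22 cell cycle genes had a median of 0.08.

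The YAP/TAZ target signature had a median of 0.05, at percentile 91.2 of random lists, with 4 of 22 members at least 1.5-fold higher and 0 lower. These were F3, tissue factor, at 1.10, the angiomotin family member Amotl2 at 0.79, the phosphatase Ptpn14 at 0.68 and Crim1 at 0.66. Ctgf had a fold of 1.13 (1.08 to 1.19) and Cyr61 1.36 (1.27 to 1.44), against folds between the controls of 1.24 for Ctgf and 0.921 for Cyr61. Of 22 Hippo pathway components, a list that holds Yap1 itself, 18 were higher with a median of 0.15, Wwc1 at 0.93, Amotl2 at 0.79 and the Yap partner Tead4 at 0.65.

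The number of 2-fold genes in the Tg pair was 164 with a pseudocount of 0.1, 24 with a pseudocount of 5, and by RPKM 7 higher and 30 lower. Between the 2 controls, 137, 14 and 30 genes were at least 2-fold different under those settings and 63 under the main one. With a minimum of 5 CPM the counts were 52 in the CKO pair, 62 in the Tg pair and 38 between the controls.

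The 2 pairs were then set against each other to ask whether loss and gain of Yap go with opposite differences. Of 13798 genes tested in both, 54 were at least 1.5-fold lower in the Yap CKO and higher in the YAP Tg, against 2.02 expected for independent lists. Another 36 were higher in the Yap CKO and lower in the YAP Tg, against 1.29 expected. In the same direction, 18 were lower in both, against 2.71 expected, and 0 were higher in both, against 0.957. Across genes, which are not independent replicates, the log2 ratios of the pairs had Pearson's r of -0.39 and Spearman's rho of -0.34. The pairs share no library, and the opposite genes numbered 152 with a pseudocount of 0.1, 36 with a pseudocount of 5 and 36 by RPKM. Tissue lists also ran opposite, with medians of -0.43 and 0.26 for dental epithelium, 0.26 and -0.57 for skeletal muscle and 0.59 and -0.84 for bone. A difference in the dissected tissue could thus give opposite genes and a negative correlation, and its part was not separated from that of genotype.

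Genes lower in the Yap CKO and higher in the YAP Tg included Wnt3a (-2.09 and 1.07) and Wnt9b (-1.23 and 1.07). Cyp2w1, a cytochrome P450, had -1.22 and 1.10, Phyhip -1.16 and 1.38, Ntn4, a basement membrane netrin, -1.01 and 1.12, and Fgfbp1 19.1 and 9.05 CPM in the CKO pair and 16.9 and 38.7 CPM in the Tg pair. Genes higher in the Yap CKO and lower in the YAP Tg included Idi2 (1.46 and -2.34), Sprr3 (1.5 and -2.28), Krt13 (1.24 and -2.05), Krt6a (1.42 and -1.88), Ly6d (1.13 and -1.65), Spink5 (1.64 and -1.40) and Sprr1a (1.33 and -1.29). Rptn had 173 and 1369 reads in the CKO pair, and the 2 controls differed in it by a fold of 1.84. Dmp1 was among them too (1.17 and -2.27), with a log2 ratio of 0.97 between the controls. Muscle and bone lists also lay in opposite directions in the 2 pairs. Krt77 was lower in both (-2.07 and -0.93), as were Shh (-0.95 and -0.62) and the median of the Hedgehog targets (-0.21 and -0.25). Shh also had a log2 ratio of 0.46 between the controls, being higher in the Tg control.

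**Figure D2:**
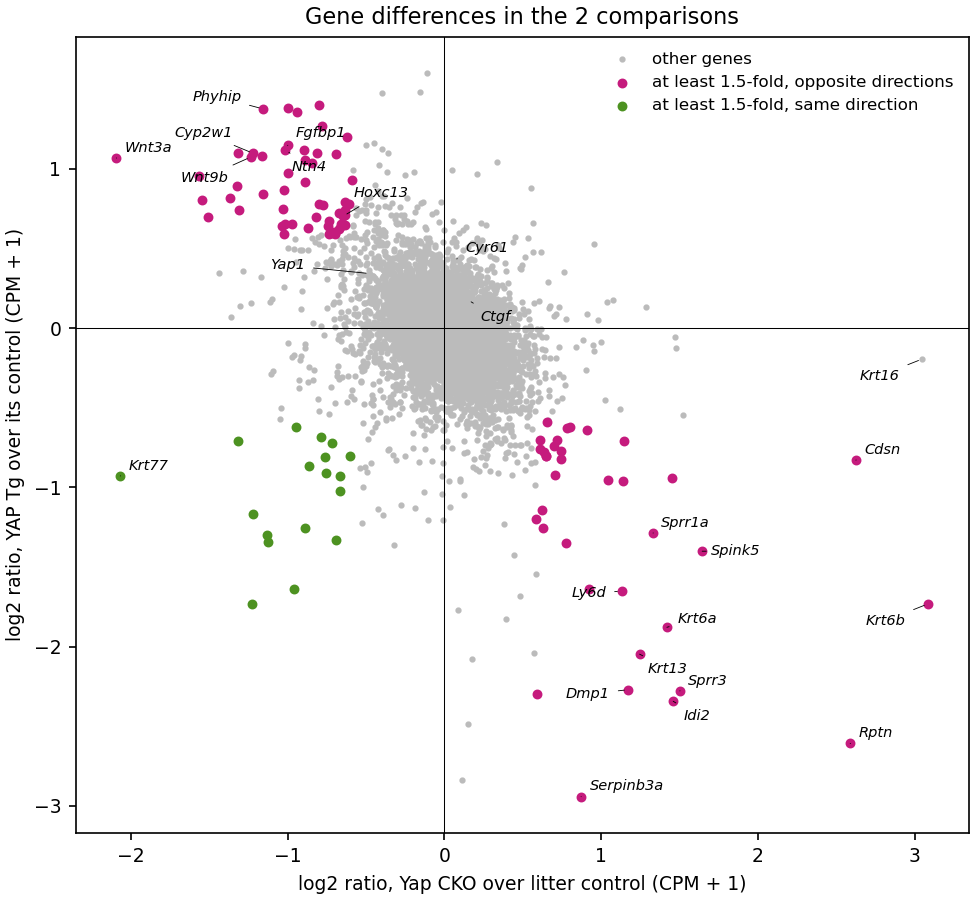
Each point is 1 of 13798 genes, with its log2 ratio (CPM + 1) in the Yap CKO pair on the x axis and in the YAP Tg pair on the y axis. The 90 genes at least 1.5-fold different in opposite directions are pink and the 18 in the same direction, each lower in both, are green. Keratins and envelope genes such as Krt13, Krt6a and Sprr3 lie at the lower right, and Wnt3a at the upper left.

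**Figure D3:**
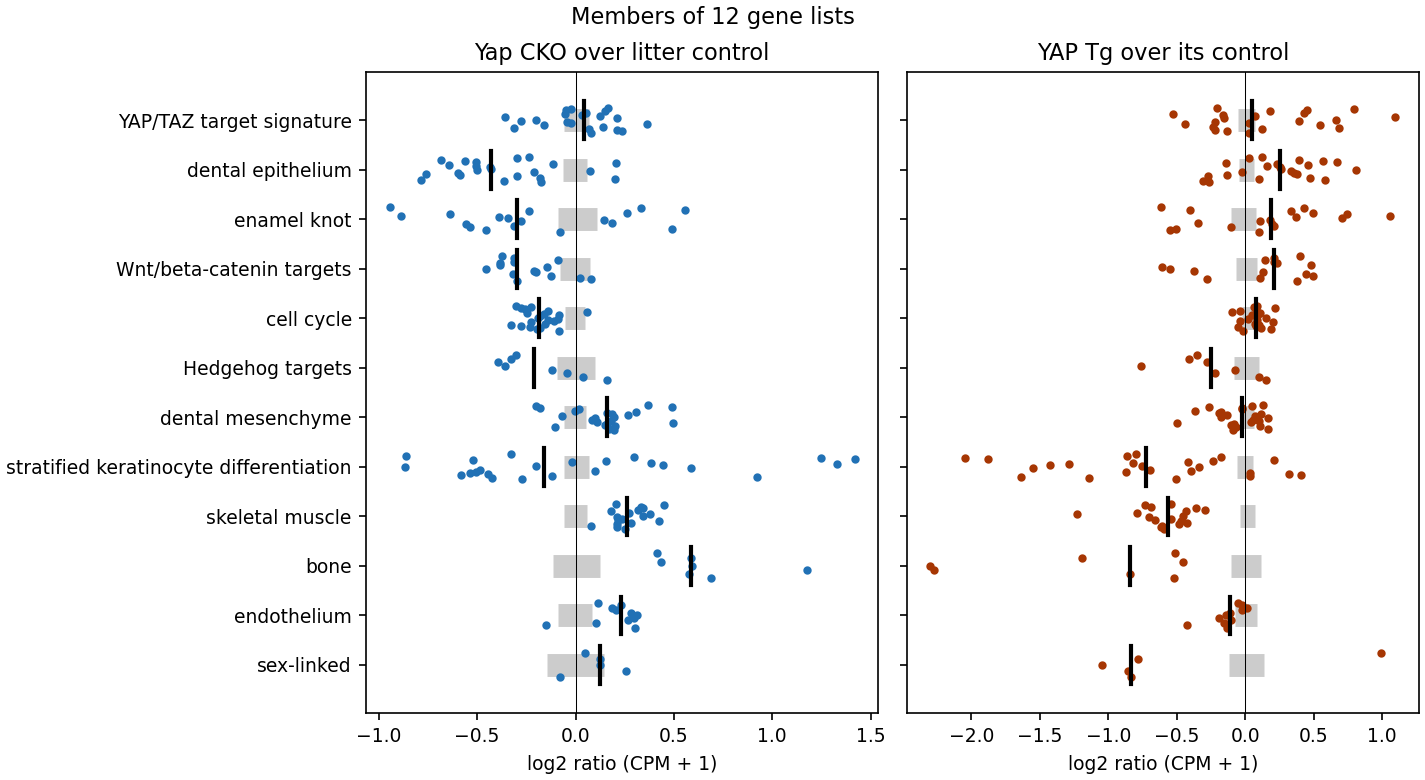
Log2 ratios (CPM + 1) of the measured members of 12 gene lists in the Yap CKO pair (left) and the YAP Tg pair (right), 1 dot per gene, with the list median as a black bar and the central 95% of medians of 10000 random lists in grey. The dental epithelium median is -0.43 on the left and 0.26 on the right, and the skeletal muscle median is 0.26 and -0.57.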

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

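The deposited RPKM, the data without X and Y genes and the data without genes of differing models were tried after seeing the data, and the other settings were fixed before the data were examined. No paired analysis was possible because each group has 1 library, and no library could be left out. Under the 3 other scalings, with no minimum, without small RNA and hemoglobin genes, without X and Y genes and without genes of differing models, each count of 2-fold genes and of opposite genes stayed within 1.5 times its main value. With a pseudocount of 1, a gene under 1 CPM in both libraries cannot be 2-fold different. Dropping the minimum therefore could not change the 2-fold counts. Yap1 kept its direction in both pairs under all 11 alternatives, though those that only choose which genes are tested cannot change its ratio. Pearson's r between the pairs lay between -0.44 and -0.36. The medians of the dental epithelium, keratinocyte differentiation, cell cycle, skeletal muscle and bone lists also kept their sign under all 11. The number of list medians outside the central 95% of random lists was 32 of 52, and between 30 and 34 under the alternatives. Lying outside is not by itself a mark of genotype. Between the 2 controls the enamel knot, cartilage, keratinocyte differentiation, erythroid and macrophage medians lay outside too. So did those of the dental mesenchyme, skeletal muscle, interferon response, neuron and sex-linked lists. The dental epithelium and cell cycle medians between the controls lay inside. The largest shift of the median of all genes was -0.036 on the log2 scale, by RPKM in the Tg pair.

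The pseudocount moved the counts most, because it decides how far genes of a few CPM can differ. With a pseudocount of 0.1 there were 151 genes at least 2-fold different in the CKO pair, 164 in the Tg pair, 137 between the controls and 152 opposite genes. With a pseudocount of 5 these were 18, 24, 14 and 36. With a minimum of 5 CPM, which tests fewer genes, 38 genes were 2-fold different between the controls, beside 52 in the CKO pair and 62 in the Tg pair. By RPKM, where a pseudocount of 1 weighs more on long genes, the counts were 32, 37, 30 and 36, the Yap1 log2 ratio in the Tg pair was 0.29 and the cell cycle median in the Tg pair was 0.034; the cause was not tested. Dtna was the only named gene to reverse, from 1.47 by counts to -0.093 by RPKM in the CKO pair, both with a pseudocount of 1, where its model length differs between the files. Depth limits genes of few reads: the 12 Hoxa1 reads in the Tg control leave a fold of 7.93 to 28.3 in that pair, and the 4 Krt6b reads in the YAP Tg a fold of 0.00749 to 0.0725, while Yap1 rests on 13140 to 20980 reads.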

Other observations

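All tests in this part, and the 3 gene lists of its first paragraphs, were chosen after the results were seen; the other lists named here were fixed before the data were examined.

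The Wnt ligand list was drawn up after Wnt3a, Wnt9b, Wnt6 and Wnt3 had been seen to differ, and counts them. Each of them passed 1.5-fold in both pairs. Of its 16 measured genes 7 were at least 1.5-fold lower in the Yap CKO and 7 at least 1.5-fold higher in the YAP Tg, with median log2 ratios of -0.39 and 0.44 and -0.04 between the controls. The 7 were not all the same, since Wnt4 passed 1.5-fold in the CKO pair only and Wnt10b in the Tg pair only. In all, 9 of the 16 were within 1.5-fold in the CKO pair and 9 in the Tg pair, and 5 lay above 0 in the CKO pair. Wnt7a had 3.42 and 0.774 CPM in the CKO pair and 3.29 and 8.19 CPM in the Tg pair. Wnt4 had log2 ratios of -0.77 and 0.52 and Wnt7b -0.64 and 0.79, while Wnt5a, the most abundant member, had 0.06 and 0.25 and Wnt11, 0.14 and -0.09. The list of hemidesmosome and epithelial laminin genes was drawn up after Itgb4 and Bcam had been seen to differ, and counts both. These genes, which anchor basal cells to the basement membrane, had medians of -0.54 and 0.55 over 12 members, with 6 at least 1.5-fold lower in the Yap CKO and 5 higher in the YAP Tg. The laminin chains Lama5 and Lamc2 had -0.78 and 0.78, and -0.66 and 0.65, and Itga3 had -0.95 and 0.41. Plec1, the cytolinker plectin, had 0.17 and 0.00 in the 2 pairs. The dental epithelium list lay in the same directions in both pairs.

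The retinoic acid metabolism list was drawn up after Cyp26c1 had been seen to differ. Its 11 measured genes had medians of 0.07 in the CKO pair and -0.20 in the Tg pair, where 3 were at least 1.5-fold lower and 8 within 1.5-fold; the difference between the pairs was not tested. Cyp26a1 had 9.21 and 4.00 CPM in the Tg pair, Cyp26c1 20.7 and 2.88 CPM, and Aldh1a2, which makes retinoic acid, 36.6 and 23.6 CPM, whereas Cyp26b1 had 94.8 and 115 CPM. The interferon response list had medians of 0.25 and -0.15, and -0.23 between the controls. Macrophage genes had 0.10 and -0.15 (controls -0.23), endothelium -0.11 in the Tg pair and erythroid genes -0.01 in the Tg pair. Neurons had 0.10 and -0.11 (controls -0.18), glia and neural crest 0.09 and 0.10, and melanocytes -0.25 and 0.02. Dental mesenchyme had 0.16 and -0.03 (controls 0.11), and the EDA and NF-kappaB pathway -0.08 and 0.10. The p53 targets had -0.00 and -0.01, and early response and heat shock genes 0.08 and 0.10. Sex-linked genes in the CKO pair had a median of 0.13, against 0.17 between the controls, and Xist had 676 and 698 CPM in the CKO pair. The largest difference between the 2 controls was in Nr1h5, with 0.335 CPM in the CKO litter control, 0.395 in the Yap CKO, 23.4 in the Tg control and 30.9 in the YAP Tg, which separates the strains and not the genotypes.

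The dental epithelium list was lower in the Yap CKO and higher in the YAP Tg. A different share of epithelium in the dissected tissue would shift its members by about the same amount if each were made only there. The standard deviation of their log2 ratios was 1.97 times that between the controls in the CKO pair and 2.19 times in the Tg pair. The controls differed in this list by a median of only 0.0035, so their spread does not show how unevenly a change of share would act. The ratios therefore cannot decide on share. In the Tg pair Krt5 and Krt14 were higher while Krt13, Krt6a and Sprr3 were lower, which a larger share of the same epithelium would not give. A different ratio of tooth to oral epithelium, or a different share of epithelium for this list, stays open. So does an effect of Yap on epithelial cells, for which replicates would be needed.

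Muscle and bone genes were higher in the Yap CKO and lower in the YAP Tg. A different amount of jaw muscle around the germs would shift all muscle genes alike. Their spread was 0.470 times that between the controls in the CKO pair and 1.04 times in the Tg pair. Without Ckm, which widens the control spread, the ratios were 0.730 and 1.09. The controls differed in this list by a median of -0.06, so their spread does not show how unevenly a change in amount would act. The ratios leave dissection open and cannot decide on it. The Tg members still ranged from -1.23 for Ckm and -0.79 for Acta1 to -0.36 for Myog and -0.30 for Myod1, so a difference in muscle maturity stays open. For jaw bone the ratio was 0.684 in the CKO pair. It was 2.18 in the Tg pair, where Spp1 and Dmp1 had -2.30 and -2.27 but Alpl -0.46 and Sp7 -0.51. The controls differed in the bone list by a median of 0.07, so their spread does not show how unevenly more or less bone would act. Dmp1, at 0.97 between the controls, also widens that spread. Whether a different amount of bone of the same maturity is the whole cause stays open in both pairs.

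Variants of the other strain background, carried by a library, would make its 2-fold genes resemble the other control, which held for 8.57% of the 70 genes in the CKO pair and 11.8% of the 76 in the Tg pair and argues against it for most of them. Among the other genes tested, 1.41% and 1.46% differed at least 1.5-fold between the controls in either direction, and the control of each pair enters both ratios, which raises the first shares by itself. Of the 6 and 9 genes concerned, several went far past the other control, which a carried variant alone would not give: Rptn had 21.6 CPM in the Yap CKO against 5.10 in the Tg control, and the YAP Tg had 0 CPM of Rptn, 2.88 of Cyp26c1 and 4.08 of Dmp1 against 2.76, 10.6 and 11.5 in the CKO litter control, while Dmp1 in the Yap CKO, at 27.3 CPM against 23.5 in the Tg control, stays open. Differing gene models could account for at most 10% of the 2-fold genes in the CKO pair and 3.95% in the Tg pair, and by RPKM without a pseudocount, which divides by each file's own model length, 9 of the 10 genes concerned were under 1.5-fold, among them Dtna, E030049G20Rik, Rbpms and Serpinb8, which also resembled the other control. Bnip2 had 2626 and 6579 reads in the CKO pair but 33.3 and 31.4 RPKM, while Serpinb10, the exception, had 3.24 and 0.892 RPKM.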
